A study of Homo sapiens with 6 samples.

How the data were processed

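The series holds 6 RNA-seq libraries of differentiated primary human epidermal keratinocytes, all exposed to poly(I:C) for 4 h: 3 control libraries (CTLi in the labels) and 3 with siRNA knockdown of ZNF750. Per the labels' protocols, cells were grown in EpiLife medium with calcium, RNA was taken with a PureLink mini kit and libraries were made with a TruSeq RNA kit. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the control cells received a non-targeting siRNA.

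The deposited table gives, per the labels and its own heading, normalized counts per gene: a signal that is never negative, with 1 column per library and no pooling. TopHat2 2.1.0, Partek 9.0.20.0202 and the genome build hg19 are named in the submitters' processing notes, without their roles. The annotation release, the scaling method and the use of strand are not given in the sources used here. The coordinates in the deposited table fit GRCh38 rather than hg19: of 18366 genes with a gene of the same symbol in GENCODE v29 on GRCh38, 18216 (99.2%) overlapped it. Coordinates are therefore printed as the table gives them and called GRCh38, with 1 subtracted from the stop, which lay 1 above the GENCODE end for 12806 genes. The table lists 19123 genes and no row without a gene, and 35 genes on the Y chromosome or XIST were left out of tables and figures of single genes.

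In each library the most frequent low values were whole multiples of 1 step, taken as the value of 1 read. Dividing by it gave estimated depths of 24134698 to 34648079 reads in the control and 26181029 to 35603701 reads in the knockdown group. Of values up to 100 reads, 64.5% in the control and 60.2% in the knockdown libraries, on average, were whole within 0.02 reads, and the rest were fractional, as when a read is divided between genes. Whole reads were therefore not recovered, and tests for counts were not applied. The deposited scaling left the medians of ratios between libraries at factors of 1.01, while the normalized counts summed to 33720793 to 34326299 in the control and 24695544 to 25681163 in the knockdown libraries. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.33 to 19.7 between pairs of a group, so each was counted as 1 sample. Where the lower group had under 1 read in all, the fold is a bound against 3 reads over the group, and with 1 to 3 reads an exact binomial interval at the 95% level is given; both cover counting error only.

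Genes with a mean of at least 10 over the 6 libraries were kept, 16966 in all. The log2 of the value plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, group as the single term), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A log2 difference is knockdown minus control on that scale, which understates the change of low genes, and folds are ratios of mean normalized counts. Gene lists with at least 3 kept genes, 27 of 29, were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01, and beside it with the correlation estimated per list and with fry. The median of each list was also set against 10000 random lists matched on mean expression. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

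The design, the tests, the gene lists, the rule for named genes and all but the last 2 alternatives below were set before the data were examined. The rule named ZNF750; the 10 genes with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05, groups that did not overlap and a mean of at least 10 in the higher group, without XIST and genes of the Y chromosome; up to 4 members of each list with the smallest p; TLR3, IFIH1, DDX58 and DHX58; and up to 3 members with the highest mean of each list of other cell types or RNA quality. Genes named outside it are said to have been chosen after their values were seen.

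The procedure was tested on simulated libraries with the real means and depths, in which 200 of 16972 genes were changed, as many up as down. Whole reads were drawn, and the spread was the median of genes of similar abundance. The procedure recovered 62% of genes changed 1.25-fold, 82% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold (50 genes each). It called 10 of 16772 unchanged genes (0.0596%). The real libraries held fractional values, unequal totals between groups and 77.7% of genes called, so these rates may not hold for them. In a second simulation the procedure called the 1 changed list and 0 of 26 unchanged lists with each list test. Genes were drawn independently of each other there, so correlation between genes was absent. That simulation therefore cannot show how often lists are called falsely in the real data, where camera's calls depended on the correlation assumed.

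The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 100, median-of-ratios scaling, TMM scaling and quantile normalization, no trend, a robust fit, array weights, a replicate block, leaving out each library, and for lists the estimated correlation, fry and ranks. Rescaling to equal totals and limma voom on the estimated reads were added after seeing the data. GC content and transcript length came from the longest GENCODE v29 transcript of a gene, for 16432 genes, and their trend was removed with a polynomial of degree 3.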

Results

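RNA sequencing was done on primary human epidermal keratinocytes that had been differentiated in culture and exposed for 4 h to poly(I:C), a synthetic double-stranded RNA that mimics a product of viral replication. Cells received an siRNA against ZNF750, a zinc-finger transcription factor of late epidermal differentiation, or served as the control (CTLi in the labels). Each group had 3 libraries, and all 6 had received poly(I:C), so the design held a single comparison, ZNF750 knockdown against control under poly(I:C). The effect of poly(I:C) itself was not analysed here. Normalized counts were given for 19123 genes. The estimated depth was 34648079, 25545954 and 24134698 reads in control replicates 1, 2 and 3, and 26181029, 27302440 and 35603701 reads in knockdown replicates 1, 2 and 3. Log2 expression correlated across genes at Pearson's r of 0.989 to 0.993 between libraries of a group and 0.873 to 0.881 between groups, and the first principal component carried 91.4% of the variance.

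ZNF750 mRNA was measured first, as the check of the knockdown. The gene lies on chromosome 17, 82829434 to 82840022, minus strand (GRCh38 coordinates), inside the span of TBCD on the opposite strand. Its normalized counts were 7643, 7198 and 6695 in the control libraries and 2786, 2913 and 2839 in the knockdown libraries. The mean fell from 7178 ± 474 to 2846 ± 63.4 (SD, n = 3 each), which left 39.6% of the control level, and the log2 difference was -1.33 (SE 0.0567; limma, Benjamini-Hochberg adjusted p = 1.66e-10). Under quantile normalization, which gives every library the same distribution of values, the log2 difference was -0.87. Reads from ZNF750 and TBCD could not be told apart by strand, since the use of strand in counting is not given in the sources used here; TBCD, chosen after its values were seen, rose from 471 ± 21.4 to 792 ± 45.7.

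The comparison asked what a lower ZNF750 level changed in keratinocytes exposed to double-stranded RNA. Genes of the interferon response, chemokines and RNA sensors rose in the knockdown cells, while genes of the cornified envelope, the lipid barrier and the late cornified envelope (LCE) and SPRR families fell. Of 16966 genes tested, 6452 were higher and 6724 lower in the knockdown at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 3322 and 2730 of these differed at least 2-fold up and down. The control and knockdown values did not overlap in 80.0% of genes, against 10% by chance for 3 against 3. The normalized counts summed to between 33720793 and 34326299 in the control and between 24695544 and 25681163 in the knockdown libraries, and when all libraries were rescaled to equal totals 9587 genes were higher and 4054 lower, a share of 70.3% higher in place of 49.0%. The 2-fold counts moved as well, to 5070 higher and 1633 lower. In the accounts of single genes that follow, every gene said to have risen or fallen had an adjusted p under 0.05, and its 3 knockdown libraries all lay on one side of the 3 control libraries except where stated.

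The 10 largest rises were in genes of several kinds, among them chemokines and interferon-induced genes. S100A7A, an S100 protein of inflamed epidermis (chromosome 1, 153416520 to 153423222), rose from 4.06 ± 0.191 to 2909.6 ± 28.9 normalized counts (SD, n = 3 each), a ratio of 717. APOBEC3A, a cytidine deaminase that acts on single-stranded DNA, rose 499-fold to 5101 ± 700.0, and GBP4, an interferon-induced guanylate-binding protein, rose 458-fold to 1542 ± 214. GBP4 had 9 reads over the control group, and without control replicate 1 it had 3 and the fold was 723 (95% interval 258 to 3664). CX3CL1, the chemokine fractalkine, rose 329-fold, and LMO2, a LIM-domain transcription cofactor, rose 248-fold. The control group held 10 reads of CX3CL1, 4 of LMO2 and 10 of S100A7A, so these folds also rest on few reads. IFIT2, CXCL10 and CXCL11 completed the coding genes among the 10 largest rises. The long non-coding RNA LINC02605 was at 0 in all 3 control libraries and at 133 ± 25.2 in the knockdown, at least 110.1-fold higher against a floor of 3 reads over the control group. Another non-coding RNA, U62317.1, had less than 1 read over the control group and was at least 334-fold higher against the same floor. These bounds cover counting error only.

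The largest falls included genes of the cornified layer. ARG1, the arginase of the urea cycle (chromosome 6, 131470832 to 131584332), fell from 1626 ± 117 to 6.32 ± 3.08 normalized counts, a ratio of 257. KPRP, a keratinocyte proline-rich protein, fell from 112742 ± 12516 to 1184 ± 132, and LORICRIN, the main protein of the cornified envelope (chromosome 1, 153259687 to 153262124), fell from 15917 ± 4601 to 180.1 ± 50.1 (SD, n = 3 each). SLC2A3, a glucose transporter, fell 86.6-fold and APOB, an apolipoprotein, 88.2-fold. The genes SHE, KCTD4 and ZNF114 fell 219-fold, 119-fold and 227-fold, with 6.58, 46 and 4 reads over the knockdown group. Without knockdown replicate 2, SHE had 2.12 reads there and the fold was 493 (95% interval 142 to 4240.0). The non-coding RNAs AC023157.2 and AL358394.2 fell 151-fold and 117-fold.

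All 4 double-stranded RNA receptors rose. TLR3, the endosomal receptor (chromosome 4, 186069155 to 186088073), rose from 10.4 ± 3.98 to 876 ± 51.1 normalized counts (SD, n = 3 each), a ratio of 84.1 (log2 difference 6.32, SE 0.213; limma, Benjamini-Hochberg adjusted p = 1.72e-11). Of the cytosolic receptors, IFIH1, which encodes MDA5 (chromosome 2, 162267074 to 162318684), rose from 675 ± 96.4 to 14672 ± 1271, DDX58, which encodes RIG-I (chromosome 9, 32455302 to 32526208), from 356 ± 34.7 to 11839 ± 1546, and DHX58, which encodes LGP2, from 53.6 ± 6.02 to 1793 ± 28.9. Of 15 pattern receptors tested, 14 rose and 1 fell, NLRP10, an inflammasome-family gene of the epidermis, from 25008 ± 2208 to 3548 ± 291. The receptor list was higher by camera (adjusted p = 2.78e-05; adjusted p = 0.224 with an estimated correlation). Of 21 adaptors and kinases below these receptors, 16 rose and 4 fell (camera adjusted p = 0.00446; adjusted p = 0.229 with an estimated correlation). Among them the transcription factors IRF1 and IRF7 rose 36.2-fold and 3.74-fold, the kinase IKBKE 15.4-fold and UNC93B1, a chaperone of endosomal Toll-like receptors, 5.76-fold.

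**Figure D1:**
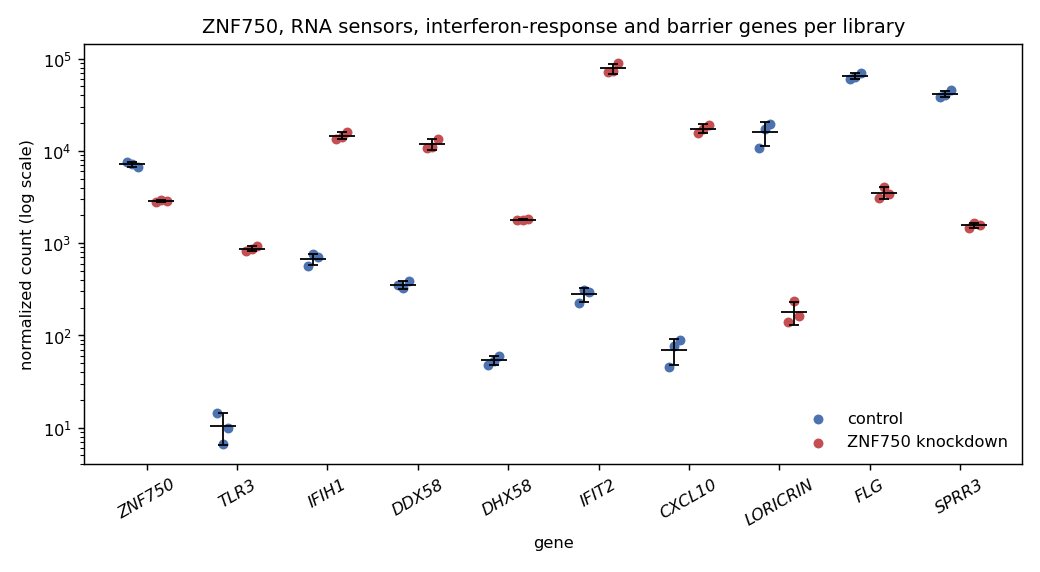
Normalized counts (vertical axis, log scale) of 10 genes in each control and ZNF750 knockdown library; points are the 3 libraries of a group, and black bars give the mean and SD. ZNF750 fell to 39.6% of control, the RNA receptors TLR3, IFIH1, DDX58 and DHX58 with IFIT2 and CXCL10 were higher in each knockdown library, and LORICRIN, FLG and SPRR3 were lower.

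All 37 interferon-stimulated genes tested rose, with log2 differences from 0.65 to 8.14 and a median of 3.93. IFIT2 and IFIT1, which bind viral RNA or block its translation, rose from 278 ± 45.4 to 78399 ± 9745 and from 344 ± 47.7 to 42667 ± 4816 (SD, n = 3 each). RSAD2, the antiviral enzyme viperin, rose 44.8-fold and its genomic neighbour CMPK2, a mitochondrial nucleotide kinase, 75.6-fold. The list was higher by camera (adjusted p = 9.97e-16; adjusted p = 0.228 with an estimated correlation). Among the interferons themselves, the lambda interferons were scarce. IFNL1 rose from 1.75 ± 2.24 to 59.5 ± 17.96, while IFNL2 and IFNL3, near-identical genes whose reads may have been divided between them, had 2 and 3 reads over the control group and rose 30.7-fold (95% interval 9.11 to 283) and 19.3-fold (95% interval 6.60 to 98.7). Most of these control reads came from 1 library, since IFNL2 had 0 without control replicate 2, and without control replicate 3 IFNL1 and IFNL3 had 1 each and were 122-fold (95% interval 19.4 to 4325) and 50.6-fold (95% interval 7.49 to 1714) higher. IFNK, a keratinocyte interferon, rose from 303 ± 15.9 to 373 ± 13.0. All 5 measured interferon genes rose, 4 under quantile normalization, and the list's camera adjusted p was 0.0473 (0.229 with an estimated correlation), within a range of 0.0344 to 0.229 over the camera alternatives. The call was lost without control replicate 1 (adjusted p = 0.0522), knockdown replicate 2 (0.122) or knockdown replicate 3 (0.0764), with a pseudocount of 0.1 (0.0902), without the filter (0.0533), under quantile normalization (0.108), equal totals (0.144) or voom (0.0542), and by ranks (0.0718); without knockdown replicate 2 the median log2 difference was 1.53 in place of 3.65. IFNB1 and the interferon alpha genes were not analysed here.

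Chemokines rose almost throughout, with 16 of 17 higher (camera adjusted p = 2.26e-06; adjusted p = 0.224 with an estimated correlation). CXCL10 and CXCL11, ligands of the chemokine receptor CXCR3, rose from 70.1 ± 21.9 to 17435 ± 1930.0 and from 22.5 ± 5.19 to 5146 ± 843 (SD, n = 3 each), and CXCL14 rose 8.72-fold. Cytokines moved both ways: 14 of 22 rose and 8 fell, and the list was not called (camera adjusted p = 0.114). TNFSF10, the death ligand TRAIL, rose 24.8-fold, LIF 48.6-fold and IL36G 5.96-fold, whereas IL18 fell from 12067 ± 1786 to 2335 ± 142. Of 17 NF-kappaB feedback and target genes, 15 rose (camera adjusted p = 2.78e-05; adjusted p = 0.224 with an estimated correlation), among them SOD2, the mitochondrial superoxide dismutase, by 12.5-fold, BIRC3 by 10.1-fold, TNFAIP2 by 6.31-fold and TNFAIP3, the NF-kappaB inhibitor A20, by 3.31-fold. Of 18 genes of MHC class I antigen presentation, 17 rose (camera adjusted p = 4.88e-07; adjusted p = 0.224 with an estimated correlation). The peptide transporter TAP1 rose 13.9-fold, the class I transactivator NLRC5 29.8-fold, TAPBP 4.02-fold and HLA-B 4.99-fold.

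The list of psoriasis-associated alarm genes and antimicrobial peptides split, with 6 of 20 members higher and 14 lower, and was not called (camera adjusted p = 0.114; 0.00885 lower after rescaling to equal totals, within a range of 0.00885 to 0.365 over the camera alternatives). S100A7A rose as above. RNASE7, an antimicrobial ribonuclease of skin, fell from 48057 ± 3894 to 3219.7 ± 271, the protease inhibitor SERPINB3 fell 11.7-fold, and the defensin gene DEFB103A, which shares its sequence with DEFB103B, fell 40.2-fold.

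Genes of the outer epidermis fell. Of 23 cornified envelope and granular layer genes, 22 fell and none rose (1 rose after rescaling to equal totals), with a median log2 difference of -3.08 (camera adjusted p = 1.38e-08; adjusted p = 0.229 with an estimated correlation). FLG, which encodes filaggrin, the keratin-aggregating protein of the granular layer (chromosome 1, 152302165 to 152325239), fell from 64504 ± 4811 to 3541 ± 520.0 normalized counts (SD, n = 3 each; log2 difference -4.19, SE 0.0907; limma, Benjamini-Hochberg adjusted p = 2.84e-13). FLG2 fell 28.4-fold, CRCT1 27.7-fold, and KLK5, a protease of desquamation, 8.44-fold. In the LCE and SPRR families, small cornified envelope proteins encoded together on chromosome 1, 24 of 25 members fell (camera adjusted p = 5.25e-09; adjusted p = 0.224 with an estimated correlation). SPRR3 fell from 41732 ± 3448 to 1567 ± 88.7, SPRR2G from 27002 ± 1027 to 1308 ± 66.8, LCE2D 59.3-fold and LCE1C 25.5-fold. The exception was SPRR2F, named after its values were seen, which rose from 28.7 ± 4.74 to 131 ± 6.79. Members of these families are similar in sequence, and the division of their reads is uncertain.

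Of 24 genes of barrier lipid synthesis, 23 fell and none rose, with 1 higher after rescaling to equal totals (camera adjusted p = 1.01e-08; adjusted p = 0.229 with an estimated correlation). CYP4F22, the hydroxylase of very long fatty acids in acylceramide synthesis, fell from 5372 ± 628 to 83.0 ± 13.9 (SD, n = 3 each). ELOVL4, a fatty acid elongase, fell 10.3-fold, SDR9C7 17.0-fold and SPTLC3, a serine palmitoyltransferase subunit, 6.62-fold. In the list named keratins of other epithelia 8 of 9 also fell (camera adjusted p = 0.00428, or 0.284 with an estimated correlation). Among them were KRT80 from 107134 ± 3468 to 9533 ± 966, KRT4 12.3-fold, KRT78 12.8-fold, KRT13 4.44-fold, KRT18 3.89-fold and KRT23 3.76-fold. KRT80, KRT23 and KRT13 were abundant in the control keratinocytes (means 107134, 43829 and 35055), so the list's name does not mark its members as foreign to these cells.

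Spinous layer genes divided, 7 of 14 higher and 6 lower, and the list was not called (camera adjusted p = 0.863); its median log2 difference was 0.20 (0.59 under quantile normalization and 0.63 at equal totals), while camera's direction was lower. CALML5, a calmodulin-like protein, fell 8.80-fold, SBSN, which encodes suprabasin, from 373995 ± 17721 to 62848 ± 5150.2, KRTDAP 3.59-fold and DMKN 2.62-fold. KRT1 and KRT10, the keratin pair of the spinous layer, were chosen after their values were seen. KRT10 rose from 56827 ± 8546 to 166174 ± 6049, while KRT1 was at 109542 ± 20138 in the control and 111709 ± 7310.4 in the knockdown group (limma, Benjamini-Hochberg adjusted p = 0.751). Of 17 basal layer genes, 13 rose and 2 fell (camera adjusted p = 0.0127; adjusted p = 0.275 with an estimated correlation). CDH3, which encodes P-cadherin, rose from 3839 ± 149 to 23695 ± 1366, KRT15 4.57-fold, and the anchoring collagens COL7A1 and COL17A1 2.90-fold and 2.16-fold.

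Of 23 epidermal transcription factors, 12 fell, 6 rose and 5 did not pass the test; the list was not called (camera adjusted p = 0.105; 0.0422 lower after rescaling to equal totals, within a range of 0.0422 to 0.532 over the camera alternatives). The counts depended on the scaling, with 12 lower and 10 higher under quantile normalization and 11 lower and 10 higher at equal totals, where the median log2 difference was -0.022 in place of -0.45. HOPX fell from 53139.6 ± 4953 to 7583 ± 602 (SD, n = 3 each), RORA 6.56-fold and PPARD 5.63-fold. The 6 genes of co-repressor partners of ZNF750 were not called as a list (camera adjusted p = 0.114), and their median log2 difference of -0.38 changed sign to 0.048 after rescaling to equal totals. HDAC2 fell 2.66-fold, HDAC1 1.74-fold and RCOR1 1.47-fold, and KDM1A rose 1.21-fold. Random lists matched on mean expression had a median of -0.358 for the co-repressor list and -0.374 for the transcription factors. The observed medians lay at percentiles 46.8 and 34.95 of these, so neither list differed from genes of like abundance.

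Of 21 cell death genes, 17 rose and 3 fell (camera adjusted p = 4.00e-04; adjusted p = 0.224 with an estimated correlation). RIPK3 and MLKL, the kinase and the effector of necroptosis, rose from 50.8 ± 6.69 to 617 ± 24.8 and from 63.4 ± 8.17 to 645 ± 19.5 (SD, n = 3 each), PMAIP1, which encodes NOXA, rose 9.75-fold, and GSDMA, the gasdermin of differentiated epidermis, fell 14.9-fold. Cell cycle genes were higher as a list, 19 of 28 up and 4 down (camera adjusted p = 0.00877; adjusted p = 0.224 with an estimated correlation), a call lost under a 10 times higher filter (0.0971) or quantile normalization (0.0938), within a range of 0.00578 to 0.224 over the camera alternatives. TOP2A rose 5.12-fold to 244 ± 16.4, MKI67 3.32-fold and TPX2 2.51-fold, while the replication licensing gene MCM7 fell 1.83-fold. Immediate-early and heat shock genes were lower as a list, 14 of 18 (camera adjusted p = 0.00618; adjusted p = 0.268 with an estimated correlation), a call lost under the 10 times higher filter (0.0607) or quantile normalization (0.15), within a range of 0.0031 to 0.268 over the camera alternatives. IER3 fell 5.05-fold, FOSL1 4.61-fold and DUSP1 2.87-fold, and ATF3 rose 8.35-fold. The unfolded protein and integrated stress response list was not called (camera adjusted p = 0.616), with 4 of 14 members higher, 5 lower and 5 not past the test. Under quantile normalization 6 were higher and 3 lower, and at equal totals 8 and 3. The members with the smallest p all fell: SESN2 3.56-fold, PPP1R15A 3.54-fold, DDIT4 2.58-fold and ATF4 1.33-fold. ATF4 was at a log2 difference of 0.10 under quantile normalization and 0.02 after rescaling to equal totals.

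Markers of other cell types and signs of RNA quality were measured beside these groups. Few of the fixed markers passed the filter: 4 of 10 fibroblast, 2 of 8 melanocyte, 2 of 7 endothelial and 3 of 12 immune and Langerhans cell markers. The others lay below the filter or were absent from the deposited table. Of 17 mesenchymal and matrix genes, 8 rose and 5 fell (camera adjusted p = 0.428), with TNC, which encodes tenascin-C, up from 31.8 ± 7.34 to 2595 ± 51.0, MMP9 up 6.23-fold and VIM down 4.28-fold. Of 4 fibroblast markers (camera adjusted p = 0.446), COL1A1 rose 2.61-fold, DCN 1.28-fold and THY1 1.97-fold, and FAP fell 3.44-fold; the DCN and THY1 calls were lost under quantile normalization (adjusted p = 0.0532 and 0.0814), within ranges of 1.05e-05 to 0.0532 and 0.000463 to 0.0814. Among melanocyte markers MITF fell from 1461 ± 100.4 to 103 ± 18.04, and PMEL was at 48.8 ± 7.17 and 49.1 ± 3.91. Among endothelial markers ERG was at 14.6 ± 3.47 and 14.5 ± 4.56, and VWF fell from 45.5 ± 6.62 to 28.2 ± 4.89, a call lost without control replicate 2 (adjusted p = 0.06), without knockdown replicate 1 (0.0671) or after rescaling to equal totals (0.303), within a range of 0.000897 to 0.303. The immune and Langerhans cell list was not called (camera adjusted p = 0.195): CD74 rose 4.81-fold to 107 ± 13.8, CD14 3.09-fold to 16.6 ± 1.33 (6.12-fold without control replicate 1), a call lost under quantile normalization (adjusted p = 0.0509, range 0.000439 to 0.0509), and CD68 was at 1913 ± 361 and 2352 ± 365 with overlapping groups, an adjusted p of 0.0441 and a range of 6.49e-05 to 0.2 over the alternatives. The CD68 call was lost without control replicate 1 (0.183) or 2 (0.0915) or knockdown replicate 2 (0.128) or 3 (0.2), with a pseudocount of 0.1 (0.0537), with no trend (0.172) and with a robust fit (0.161).

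Mitochondrially encoded genes rose, 12 of 13 and 13 of 13 adjusted over the list alone (camera adjusted p = 4.00e-05; adjusted p = 0.284 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, rose from 136797 ± 6902 to 351264 ± 11064 normalized counts (SD, n = 3 each), MT-CO2 2.26-fold, MT-CO3 3.11-fold, MT-ND3 2.56-fold, MT-ND4 2.04-fold, MT-ND5 2.80-fold and MT-CYB 2.46-fold. Replication-dependent histones were lower as a list, 7 of 9 (camera adjusted p = 0.0406; adjusted p = 0.268 with an estimated correlation), a call lost without control replicate 1 (0.0612), without control replicate 2 (0.0817), under the 10 times higher filter (0.147) or with the replicate block (0.0863), within a range of 0.0075 to 0.268 over the camera alternatives. H2BC5 fell 3.01-fold, H1-2 3.10-fold, H2BC21 2.34-fold, H4C8 2.30-fold and H2AC6 1.45-fold, the last call being lost under quantile normalization (adjusted p = 0.0903) or after rescaling to equal totals (0.2), within a range of 4.59e-07 to 0.2. Of 15 reference genes, 6 rose and 7 fell (camera adjusted p = 0.872). TFRC rose 2.51-fold, B2M 2.40-fold and ACTB 1.43-fold, PGK1 fell 2.41-fold, and EEF1A1 was at 116057 ± 6968 and 109724 ± 2519, with a log2 difference of -0.08 that became 0.27 under quantile normalization and 0.35 after rescaling to equal totals.

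Over the 27 lists tested, 11 were higher and 6 lower by camera with its preset correlation of 0.01, 10 were not called, and 0 were called with an estimated correlation, for which 5 had an unadjusted p under 0.05 and the smallest adjusted p was 0.224. The counts of members that rose and fell, adjusted over the list alone, equalled those adjusted over all genes except for 1 further call each among the mitochondrially encoded, immediate-early and mesenchymal genes. At equal totals 1 gene fell among the receptor adaptors and kinases in place of 4, 1 among the cell death genes in place of 3, 1 among the basal layer genes in place of 2 and 1 among the mesenchymal genes in place of 5, while 9 reference genes rose and 4 fell in place of 6 and 7. The labels do not say whether the 3 libraries of a group came from separate cultures or donors, so the p-values measure the spread between these libraries, which may be technical.

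**Figure D2:**
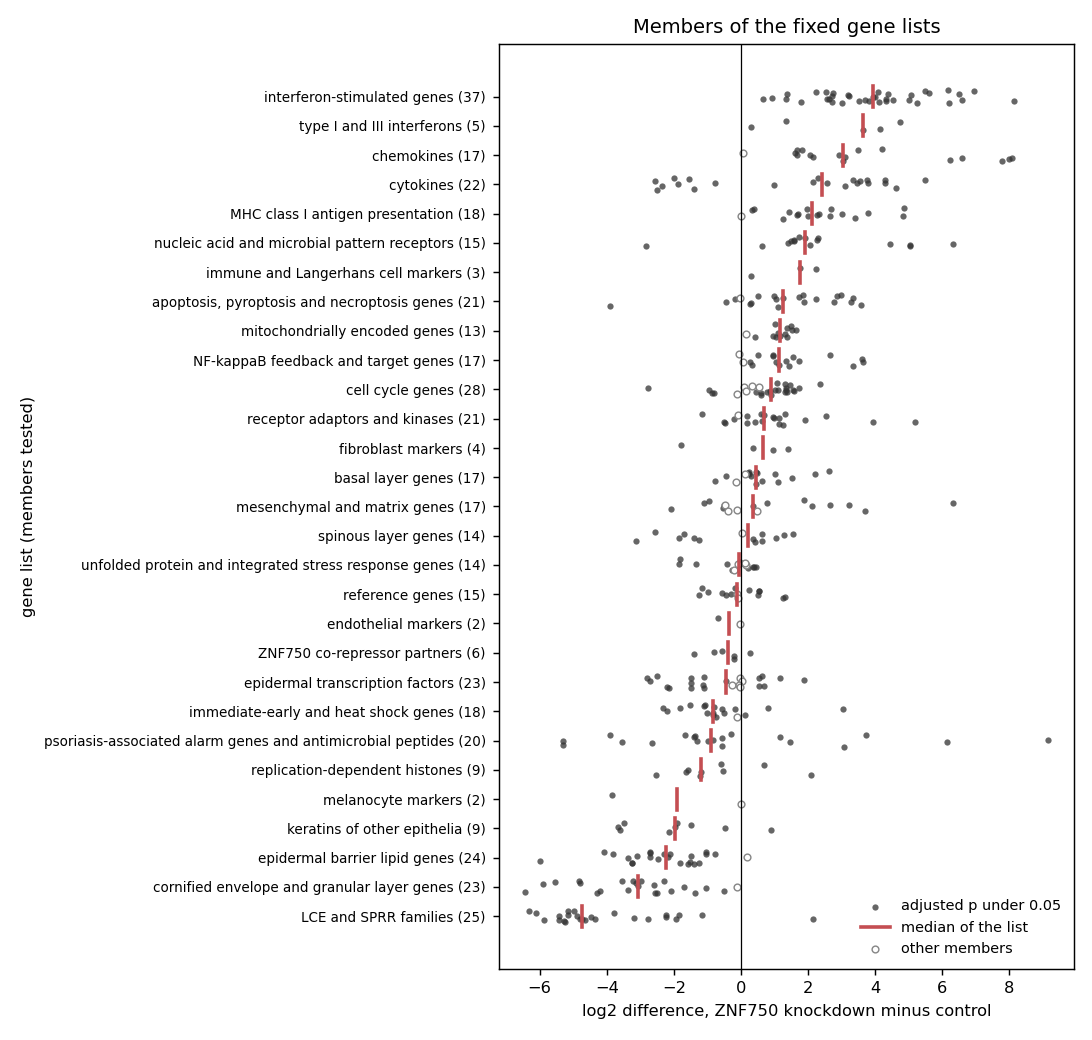
Log2 difference between ZNF750 knockdown and control (horizontal axis) of each tested member of the 29 fixed gene lists (vertical axis, number of members in brackets); filled points had an adjusted p under 0.05, open points did not, and red bars mark list medians. The interferon-stimulated genes had the highest median, 3.93, and the LCE and SPRR families the lowest, -4.73.

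**Figure D3:**
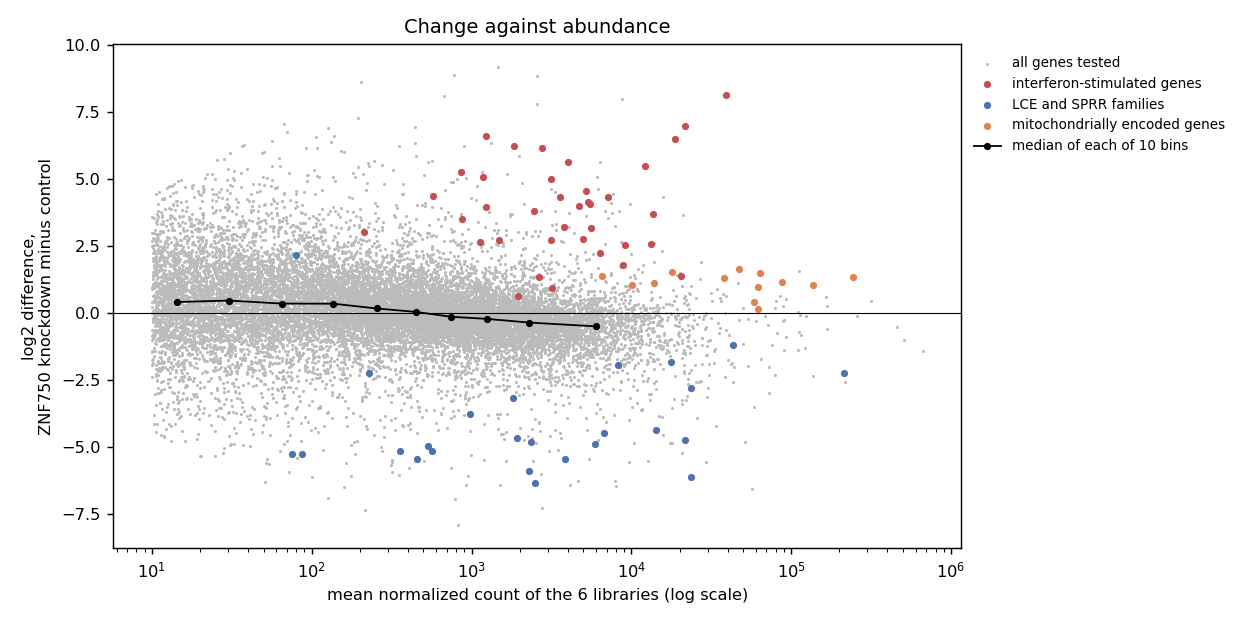
Log2 difference between ZNF750 knockdown and control (vertical axis) against the mean normalized count of the 6 libraries (horizontal axis, log scale), with 3 gene lists in colour and the median of each of 10 bins of genes ordered by count as a black line. The median was 0.41 in the bin with the lowest counts and -0.50 in the bin with the highest.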

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

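Equal-total scaling and voom were chosen after seeing the data; the other alternatives were planned. ZNF750 stayed lower under every alternative, with log2 differences from -1.38 to -0.87 over the planned ones. Of the values of named genes over all alternatives, 2551 kept their side of the threshold, which includes any change of sign that passed it in neither fit. A further 15 fell short of the threshold, and 4 reversed: ATF4 (0.104 and 0.0201) and EEF1A1 (0.268 and 0.351) under quantile normalization and equal-total scaling. Of the list values, 546 stayed on their side of the threshold, which includes lists that were called in neither fit, 34 lost their call and 10 gained one. A filter 10 times higher gave 4221 genes higher and 1562 at least 2-fold higher, from fewer genes tested (11785). Equal-total scaling moved the median log2 difference of all genes from -0.017 to 0.42 and gave 4054 genes lower, 5070 at least 2-fold higher and 1633 at least 2-fold lower; of its 13641 calls, 11070 were shared with the reported ones and 10506 of those had the same direction. The estimated correlation called 0 lists higher and 0 lower, and fry, which tests a list on its own and not against other genes, called 15 higher and 10 lower. Leaving out 1 library at a time gave 5958 to 6494 genes higher, 6351 to 6576 lower, 3173 to 3435 at least 2-fold higher and 2667 to 2804 at least 2-fold lower, with 10 to 11 lists higher and 5 to 6 lower. Causes of the other changes were not tested.

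Libraries with the same replicate number did not deviate together: over 10013 genes the correlations were 0.155, 0.138 and -0.162 for numbers 1, 2 and 3, and control replicates 1 and 3 correlated best with another number. With the replicate block 6450 genes were higher and 6693 lower, ZNF750 had a log2 difference of -1.33, and the histone list lost its call (camera adjusted p = 0.0863, range by camera 0.0075 to 0.268). edgeR and DESeq2 were planned only for whole reads and were not run, since whole reads could not be recovered. Depth limits genes near the filter, such as the lambda interferons.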

Other observations

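Gene groups in this paragraph and the next were chosen after their values were seen, so they are given as counts of genes past the test, without a test of the group. Most genes of glycolysis and glucose uptake fell in the knockdown, 18 of 20 with a median log2 difference of -1.40, or -0.84 under quantile normalization and -0.97 at equal totals. HK2, a hexokinase, fell from 29177 ± 6669.6 to 1974 ± 123 normalized counts, PFKFB3 from 10599.8 ± 1809 to 241 ± 34.4 and LDHA, a lactate dehydrogenase subunit, from 66125 ± 4515 to 17786 ± 1094 (SD, n = 3 each), while PFKL rose from 1347 ± 140.1 to 3422 ± 252. Of 24 genes of cholesterol synthesis and uptake, 21 fell. INSIG1 fell from 3354 ± 67.3 to 433 ± 22.7, while LSS rose from 1354 ± 101 to 2956 ± 167.

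In several gene families most members changed in 1 direction, and in others the members were divided. All 6 guanylate-binding proteins rose, as did all 6 APOBEC3 deaminases, APOBEC3G from 4.48 ± 1.99 to 183 ± 7.29. TRIM proteins were divided, with 27 of 46 up and 14 down. Collagens rose in 18 of 23, COL4A5 from 1019 ± 17.4 to 3262 ± 70.2. Kallikreins, the serine proteases of desquamation, fell in 11 of 12, KLK6 from 9143 ± 572 to 118 ± 18.5. All 8 pregnancy-specific glycoproteins, similar genes between which reads may be divided, fell, PSG4 from 37552 ± 624 to 3932 ± 218. Dual-specificity phosphatases fell in 10 of 17 and rose in 3, or 6 at equal totals, DUSP4 from 1645 ± 25.8 to 211 ± 11.5, and TMPRSS serine proteases fell in 6 of 7. The median of each of these 10 groups kept its direction under median-of-ratios, TMM, quantile and equal-total scaling. Median-of-ratios and TMM hardly moved these medians, and equal totals raised all of them by too little to reverse a fall. Only quantile normalization could thus have changed a direction. Some members, such as GBP1 and KLK5, also belong to the fixed lists.

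Of the tests of the 3 patterns that follow, that of group-wide handling and that of the nuclear respiratory chain genes were chosen only after the result was seen. The interferon-stimulated genes rose and the cornified envelope, LCE and SPRR genes fell in the same libraries. The trend with GC content and transcript length held 0.62% of the variance of the log2 difference over 16432 genes. With that trend removed the interferon-stimulated genes kept a median log2 difference of 3.85 (interquartile range over the root of their number, 0.392). The cornified envelope, LCE and SPRR genes kept one of -3.36 (0.363). So weak a trend could hardly move these medians, so only a bias shared by all genes was argued against. A bias particular to these genes was not tested. Handling, exposure to poly(I:C) or an siRNA reagent shared by every library of a group cannot be told apart from the loss of ZNF750, because there were 0 libraries without poly(I:C) and a single label for the siRNA. A role of ZNF750 in restraining the response to double-stranded RNA stays open as a hypothesis, as does a response to the siRNA itself, which is also a double-stranded RNA; neither was tested, since that needs knockdown libraries without poly(I:C) and a further siRNA beside a non-targeting control.

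Mitochondrially encoded genes rose. Scaling between libraries was argued against, since the lowest list median over 4 other scalings was 1.18 (interquartile range over the root of the number of genes, 0.0921). Of these, median-of-ratios and TMM hardly moved the median log2 difference of all genes (-0.014 and -0.00015), and equal totals raised it to 0.42. Only quantile normalization could thus have lowered the list. The trend with GC content and transcript length over all genes was argued against too, since after its removal the median was 1.40 (0.122). These 13 genes could hardly shape that trend, so a bias particular to them was not tested. A joint rise of the respiratory chain was argued against by the 74 nuclear genes of its complexes, whose median log2 difference was -0.059 (0.0578), with 17 higher and 30 lower; at equal totals 51 were higher and 6 lower with a median of 0.37, against 1.60 for the mitochondrially encoded genes, so a smaller joint rise depends on the scaling. RNA quality and handling shared by a group stay open, and no other biological explanation was tested.

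More genes fell than rose among the abundant ones, 1153 and 357 of 1697 in the most abundant of 10 bins, and more rose than fell among the scarce ones, 635 and 316 of 1697 in the scarcest, with a slope of the log2 difference on the log2 mean of -0.123 over 16966 genes. Sequencing depth was argued against: between the libraries of a group that differed most in depth, the steepest slope was 0.00783. With the GC content and transcript length trend removed the slope was -0.133, so that trend did not account for most of it. Without the 109 genes of the fixed epidermal differentiation lists it was -0.117. So few genes could hardly move a slope over 16966, so a wider fall of abundant differentiation genes was not tested. The authors' scaling method is not given, but the whole multiples among the most frequent low values point to a single factor per library. Such a factor moves all genes by about the same amount, so it would set where falls turn into rises and not the slope. A scaling of another form was not tested. Handling shared by a group stays open, and whether the total RNA per cell changed was not tested.

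The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 13176 genes and 6052 at least 2-fold, and 1 of the 10 divisions, the real one, reached each count; the highest of the others was 0 by limma for both, with 15 to 59 genes at an unadjusted p under 0.05. Each of the other divisions put libraries of both groups on both sides, so the group difference became spread within a side. Few calls were thus built in, and these counts are no measure of calls by chance. For camera with its preset correlation the real division called 17 lists, and 1 of the 10 reached that, but the highest of the other divisions called 16. The other divisions still held part of the group difference, so that count is not a rate of false list calls.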
